A study of Rattus norvegicus with 21 samples.

How the data were processed

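Copy number was measured by comparative genomic hybridisation on 21 two-colour oligonucleotide arrays, 1 per rat mammary carcinoma. Per the labels, tumour DNA was labelled with Cy5 and a common reference, ear DNA of female Sprague-Dawley rats, with Cy3, after digestion with AluI and RsaI. No array had its dyes swapped, so a dye effect common to all arrays remains in the ratios. Per the file headers, spots were read with Agilent Feature Extraction 9.5.1.1 and probe positions are those of the rat assembly rn4 (RGSCv3.4). The deposited spot intensity used here is the processed signal of each channel, which per the file headers had been background-subtracted, spatially detrended and scaled between dyes by linear factors, without lowess. The deposited median spot and background intensity, with no correction, served for 1 alternative. The deposited log10 ratio of Cy5 over Cy3 was used for comparison with the series matrix. The deposited series matrix holds log2 ratios. Against the scanner values its columns had correlations of 0.997 to 0.999, slopes of 0.995 to 0.999 and medians of -0.00755 to 0.0141, which settles its scale and direction, while the centring behind its small medians is not given in the sources used here.

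Each array carried 105014 spots, of which 5041 controls were left out. The 99973 probe spots represent 97973 probes, and repeated spots were averaged. Spots flagged as outliers (87 to 594 per array) were removed and saturated spots were kept. The 95593 probes placed on chromosomes 1 to 20 and X, with a median spacing of 19.1 kb over 2718 Mb, were used. Median signals stood 8.51 to 16.1 times above background in Cy3 and 10.0 to 15.9 times in Cy5. The number of arrays limits the precision.

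The log2 ratio of the processed signals was centred on the median of each array, with no loess or quantile step, because real copy number changes can shift many probes one way. The noise SD of an array was taken from differences between neighbouring probes. The SE of the mean of a stretch or chromosome in 1 tumour is this SD divided by the square root of its number of probes. It leaves out the spread of the probes within the stretch. Chromosomes were divided by recursive circular binary segmentation at a Z of 6. A call was a segment of at least 5 probes with a mean log2 ratio of at least 0.2 in size. A large call spanned at least 1 Mb and 10 probes, and all other calls are named focal. A whole-chromosome aberration needed a median log2 ratio of at least 0.2 in size and 80% of the probes in calls of that sign. A recurrent region was a stretch of at least 5 probes called with the same sign in at least 2 rats.

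The 21 tumours came from 19 rats by their tumour numbers: replicates 4 and 7 of the tumours irradiated at 3 weeks shared a rat, as did replicates 2 and 3 of those irradiated at 7 weeks. Other tumours came from separate rats. Spontaneous replicates 5 to 7 carry no replicate number in their labels and were numbered in order of deposition. Values per tumour were compared by exact two-sided permutation tests of the difference in means, counts of tumours by Fisher's exact test, and families of tests were adjusted by Benjamini-Hochberg. Intervals of differences are 95% bootstrap intervals from 10000 resamples. Positions along the genome were compared with limma 3.58.1 (R 4.3.3) in 1 fit of the 3 groups. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and numba 0.67.0.

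The genome-wide fit had been planned per gene. The files carry no gene names and the gene table at hand belongs to another assembly, so 2728 bins of 1 Mb with at least 3 probes took the place of genes. For the same reason no gene list was tested, no gene was placed in a call, and the planned test of 1 tumour suppressor locus, the restriction to genes with several probes and the correction for GC content were not run. Gene names below are background on which chromosome carries a gene. Named bins follow a rule set before the data were examined: with fewer than 5 bins past the threshold, the 5 smallest p in each direction, at most 1 per chromosome. Up to 12 recurrent regions were to be named, taken by tumour count and then by width.

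All irradiated tumours were read on scanner 1, over 4 scan days, and all spontaneous tumours on scanner 2, over 2 scan days. Scanner and group therefore cannot be told apart. Tumours irradiated at 3 and at 7 weeks shared scan days 1 and 2, and values within those days are given. Each slide held tumours of 1 group, so the slide entered limma as a random block and was not used for single values.

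Alternatives set before the data were examined were another background correction (normexp with an offset of 50, on median signals because mean signals were not used here), the series matrix values, dim probes left out, another centring, other segmentation thresholds and sizes, 1 Mb bins in place of segmentation, shared segments left out, 1 value per rat, blocks for slide, scan day and replicate number, other limma settings, and each tumour left out in turn. The normexp values kept the flagged outlier spots and had no spatial detrending or linear dye factors. They thus differ from the main values in more than the background step. Choices made after the values were seen were the subtraction of probe medians, equalised noise, joined calls, single probes, the replicate numbers without their block, a smaller limit for chromosome-wide shifts (6 robust SDs) and a rule for calls of at least 10 probes that stand apart from the other tumours. That rule at first used means alone, and the same requirement on medians was added after the comparison by means had been seen, when some low means proved to rest on a few probes. Both versions are reported.

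The procedures were tested on simulated data. With Gaussian noise on 95593 probes the segmentation gave 0 false calls over 21 arrays. With the measured residuals shuffled along the genome it gave 355 false focal and 0 false large calls, on average 11.6 per irradiated and 27.4 per spontaneous array. Implanted segments of log2 0.5 were found in 92.9% to 100% of arrays from 5 probes upward, and those of 0.25 in 92.9% to 100% from 20 probes upward. Those of 0.25 over 10 probes were found in 5 of 14 irradiated arrays (35.7%) and 5 of 7 spontaneous arrays (71.4%). Sensitivity to short segments thus differed between the groups. Those of 0.1, below the limit of 0.2 for a call, were found in 0%. For the comparison of irradiated with spontaneous tumours over 2728 bins, limma recovered 72% of bins changed by 0.05 and 100% of bins changed by 0.1 or more, with 9 false calls. The simulated bins were independent, had Gaussian noise of equal size in all groups and no effect of scan day or scanner. The measured arrays differ in this, so these rates need not hold for them.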

Results

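DNA copy number was profiled in mammary carcinomas of female Sprague-Dawley rats, an outbred strain prone to mammary tumours. The study addressed which copy number aberrations are specific to radiation-induced as opposed to spontaneous carcinomas. Of the 21 tumours, 7 arose after 2 Gy of gamma rays at 3 weeks of age, 7 after the same dose at 7 weeks, and 7 arose spontaneously. They are named below as 3-week, 7-week and spontaneous tumours with their replicate numbers. All values are log2 ratios of tumour over reference DNA at 95593 probes, centred on each array's median, and positions refer to rn4. A copy gained in every cell gives 0.58 and a copy lost in every cell -1 on this scale. Noise between neighbouring probes was 0.142 ± 0.0236 (SD, n = 14) in irradiated and 0.108 ± 0.00644 (SD, n = 7) in spontaneous tumours, a difference beyond the spread between arrays (exact permutation p = 0.00188). The test took arrays as independent, but noise varied with scan day. Means per group and scan day were 0.118 to 0.167 in irradiated and 0.106 to 0.112 in spontaneous tumours. No scan day held both irradiated and spontaneous tumours. Irradiated and spontaneous tumours were also read on different scanners.

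The broadest change was a gain of chromosome 4. The mean log2 ratio of its 6978 probes was 0.32 ± 0.00203 (SE) in 3-week replicate 3, which was the 1 tumour past the limit for a whole-chromosome aberration. Smaller elevations of the whole chromosome were measured in 3-week replicate 1 (0.16 ± 0.00175), 7-week replicate 1 (0.099 ± 0.00146) and spontaneous replicate 1 (0.041 ± 0.00131). In each of these tumours all 10 windows of 20 Mb along the chromosome lay above the probes' median over the tumours. In 3-week replicate 3 the windows lay 0.29 to 0.32 above it, and in spontaneous replicate 1 by 0.021 to 0.040. Chromosome 10 averaged 0.13 ± 0.00178 in 3-week replicate 5, with windows 0.10 to 0.11 above the median.

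**Figure D1:**
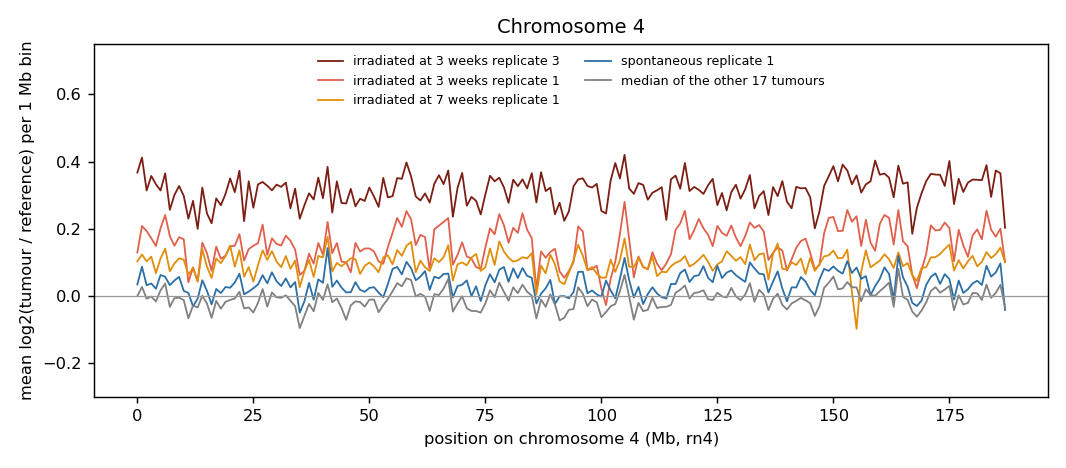
Mean log2 ratio of tumour over reference DNA (y axis) in 1 Mb bins along chromosome 4 (x axis, Mb, rn4) for 3-week replicates 3 and 1, 7-week replicate 1, spontaneous replicate 1 and the median of the other tumours (lines). The 4 tumours average 0.32, 0.16, 0.099 and 0.041 over the chromosome.

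Whole-chromosome aberrations were thus called in 1 of 14 irradiated and 0 of 7 spontaneous tumours (Fisher's exact p = 1). With a limit of 6 robust SDs, which was chosen after the values were seen, 4 of 14 irradiated tumours and 1 of 7 spontaneous tumours had a shifted chromosome (Fisher's exact p = 0.624). The spontaneous tumour lay at 6.28 robust SDs, close to the limit, and the next value below the limit was 5.60. With a limit of 10 the counts were 4 and 0, and the difference went from 14.3 to 28.6 percentage points (Fisher's exact p = 0.255). Of the 4, 3 were 3-week tumours and 1 was a 7-week tumour (Fisher's exact p = 0.559). Group means of chromosome 4 were 0.036 ± 0.0962 (SD, n = 14) in irradiated and 0.0030 ± 0.0186 (SD, n = 7) in spontaneous tumours, a difference within the spread between tumours (exact permutation p = 0.461). None of the 21 chromosomes differed between these groups (smallest adjusted exact permutation p = 0.874), and 0 had an unadjusted p under 0.05.

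**Figure D2:**
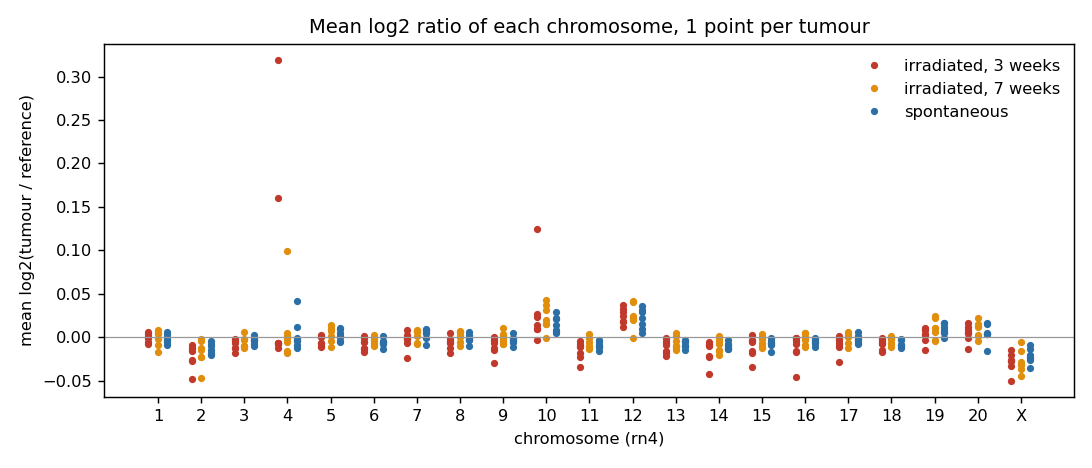
Mean log2 ratio of tumour over reference DNA (y axis) of each chromosome (x axis), 1 point per tumour, coloured by group. The points farthest from 0 are chromosome 4 in 3-week replicates 3 (0.32) and 1 (0.16) and chromosome 10 in 3-week replicate 5 (0.13).

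The deepest loss was a focal one on chromosome 5, from 108853631 to 109226886, in 3-week replicate 1. Its 17 probes averaged -2.46 ± 0.0355 (SE), or -1.79 with normexp, below the value of -1 for 1 copy lost in every cell. A loss of -0.82 ± 0.0346 over 21 probes, from 108581106 to 109023589, was called in 3-week replicate 4. In the other tumour of that rat, 3-week replicate 7, the same probes averaged 0.018 ± 0.0281. Over the 13 probes of the shared part, from 108853631 to 109023589, the means were -2.51 and -0.82, while 3-week replicate 7 lay at -0.0061. Loss in this stretch was thus called in 2 of 14 irradiated and 0 of 7 spontaneous tumours. Its mean was -0.24 ± 0.691 (SD, n = 14) and -0.0023 ± 0.0176 (SD, n = 7) (exact permutation p = 0.639). The difference rests on 2 tumours of a stretch chosen for their calls. Such a test could not give a small p and does not decide whether the groups differ. Whether the stretch includes Cdkn2a and Cdkn2b, cell cycle inhibitor genes of chromosome 5, was not established, since genes were not placed on this assembly.

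**Figure D3:**
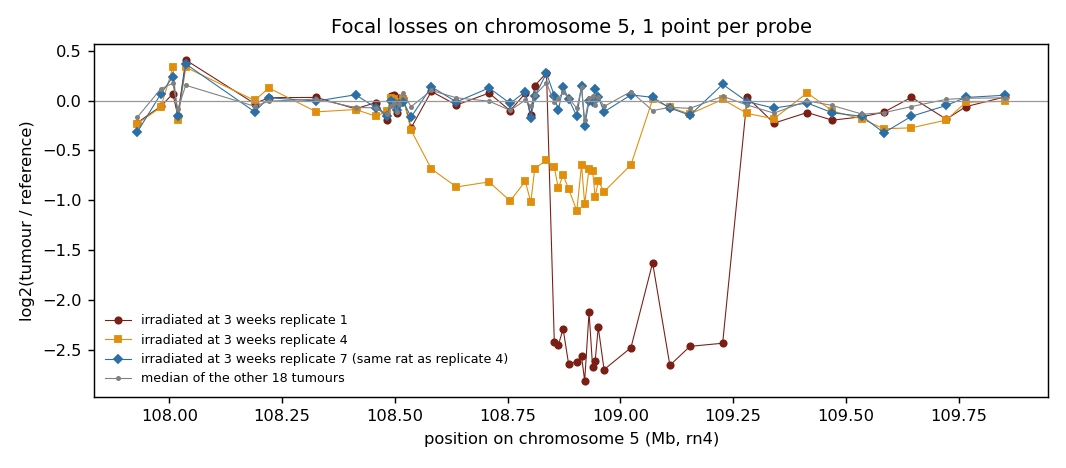
Log2 ratio of tumour over reference DNA (y axis) of each probe along part of chromosome 5 (x axis, Mb, rn4), in 3-week replicates 1, 4 and 7 and as the median of the other tumours. Replicates 1 and 4 drop to means of -2.46 and -0.82 within their calls, and replicate 7, from the rat of replicate 4, averages 0.018.

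On chromosome 3, 52 probes from 111761402 to 113371553 averaged -0.65 ± 0.0210 (SE) in 7-week replicate 5. The next lowest value there, -0.13 ± 0.0164, belonged to 7-week replicate 7 and made no call. The spontaneous tumours lay between 0.011 and 0.024. Other losses whose mean and median both lay at least 0.15 beyond the range of the tumours without an overlapping call, a rule set after the values were seen, were on chromosome 4 from 93338466 to 93670829 in 7-week replicate 3 (-0.48 ± 0.0343) and on chromosome 3 from 46832420 to 47064766 in 7-week replicate 4 (-0.33 ± 0.0477). In 7-week replicate 6 they were on chromosome 5 from 134136904 to 134571012 (-0.55 ± 0.0410) and on chromosome 7 from 5157416 to 6196810 (-0.68 ± 0.0319). The former stretch had calls in 14 of the 21 tumours, with spontaneous tumours among them, and was set against the other 7. The latter had calls in 12 tumours and was set against the other 9. In 7-week replicate 6 its probes ran from -3.62 to 0.50, a spread that the SE, taken from array noise, leaves out. For the chromosome 4 loss, 7-week replicate 2 of the same rat averaged -0.017 ± 0.0219. Gains of this kind were on chromosome 1 from 205294853 to 205995061 (0.32 ± 0.0180) and on chromosome 3 from 158873263 to 159347686 (0.27 ± 0.0304), both in 3-week replicate 6. The 1 call in a spontaneous tumour that met this rule was a gain on chromosome 10 from 87086408 to 87272372 in replicate 1 (0.32 ± 0.0273).

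Counted over calls of at least 10 probes, 14 of 60 calls had a mean and a median at least 0.15 outside the range of the tumours without an overlapping call. They were 13 in irradiated tumours, 4 of them pieces of the chromosome 4 gain of 3-week replicate 3, and 1 in spontaneous tumours. That makes 0.929 ± 1.14 (SD, n = 14) and 0.143 ± 0.378 (SD, n = 7) per tumour, a difference within the spread (exact permutation p = 0.103). Both versions of this rule were set after the values were seen. By the mean alone there were 20 calls, 14 in irradiated and 6 in spontaneous tumours, or 1.00 ± 1.18 and 0.857 ± 1.07 per tumour (exact permutation p = 0.849, n = 14 and 7). Between 3-week and 7-week tumours the counts were 8 and 5 by both measures (exact permutation p = 0.702) and 8 and 6 by the mean alone (exact permutation p = 0.848).

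The number of large calls per tumour was 1.43 ± 1.70 (SD, n = 14) in irradiated and 0.429 ± 0.787 (SD, n = 7) in spontaneous tumours. The difference of 1.00 (95% interval 0 to 2.07) did not exceed the spread between tumours (exact permutation p = 0.178), with normexp background correction it was -0.143, with probe medians subtracted 0.571, and without 3-week replicate 3 0.648. With 1 Mb bins in place of segments it was 1.93 (exact permutation p = 0.117), and the smallest p over 18 alternatives was 0.0572, with dim probes left out and a difference of 1.07. In the main count the chromosome 4 elevations of 3-week replicates 3 and 1 entered as several large calls each. Large calls covered 0.641% ± 1.96 of the probes in irradiated and 0.0129% ± 0.0296 in spontaneous tumours (exact permutation p = 0.404, n = 14 and 7). The irradiated value rested on 3-week replicate 3, with 7.37%, and without it the difference fell from 0.629 to 0.111 percentage points. At least 1 large call was present in 10 of 14 irradiated and 2 of 7 spontaneous tumours (Fisher's exact p = 0.159). This last comparison moved across the threshold with the processing: its difference of 42.9 percentage points became 57.1 with dim probes left out (Fisher's exact p = 0.0180), 64.3 with 1 Mb bins in place of segments (Fisher's exact p = 0.00712), 54.8 without spontaneous replicate 4 or 5 (Fisher's exact p = 0.0498) and -21.4 with normexp. It also shrank, to 14.3 with shared segments left out or a log2 limit of 0.15 and to 7.14 with large calls counted from 0.5 Mb. With probe medians subtracted, an alternative added after the values were seen, large calls were left in 21.4% of irradiated and 14.3% of spontaneous tumours, a difference of 7.14 percentage points (Fisher's exact p = 1). Each of the spontaneous tumours was read on the other scanner, so group and scanner cannot be told apart.

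**Figure D4:**
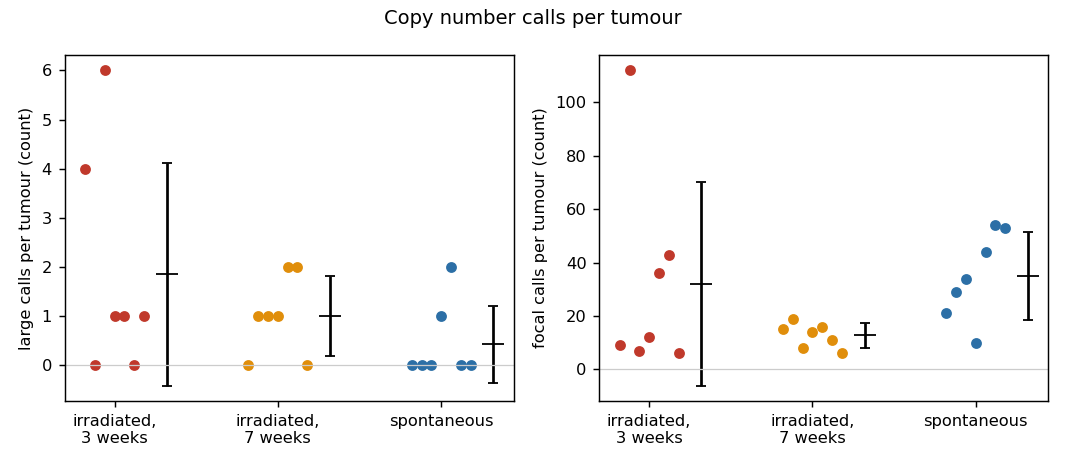
Large calls (left y axis, count) and focal calls (right y axis, count) of each tumour (points) by group (x axis), with the mean and SD of the 7 tumours of a group (bars). Large calls averaged 1.86 in 3-week, 1.00 in 7-week and 0.429 in spontaneous tumours, and the highest focal count is 112 in 3-week replicate 2.

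Much of this count came from stretches whose ratio leaned the same way in every tumour. The gain on chromosome 1 from 50367805 to 53016222 made 7 of the 23 large calls, 6 in irradiated and 1 in spontaneous tumours. Its 18 probes averaged above 0 in all 21 tumours, at 0.20 ± 0.0466 (SD, n = 14) in irradiated and 0.18 ± 0.0197 (SD, n = 7) in spontaneous tumours (exact permutation p = 0.218). At the start of chromosome 7, from 2562954 to 8253210, large losses were called in 5 irradiated tumours and 1 spontaneous tumour. That stretch averaged below 0 in all 21 tumours, at -0.13 ± 0.0531 and -0.098 ± 0.0447 (exact permutation p = 0.152, n = 14 and 7). Within it, the 28 probes from 5157416 to 6196810 averaged -0.68 in 7-week replicate 6 and -0.42 in spontaneous replicate 5. With normexp these means were -0.20 and -0.30, and with dim probes left out the latter was -0.25. The medians in the main processing were -0.37 and -0.082, and 8 and 5 probes lay below -1, against 0 to 3 in the other 19 tumours. The median of -0.37 was itself the lowest of the 21 tumours, followed by -0.30 in 3-week replicate 3.

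**Figure D5:**
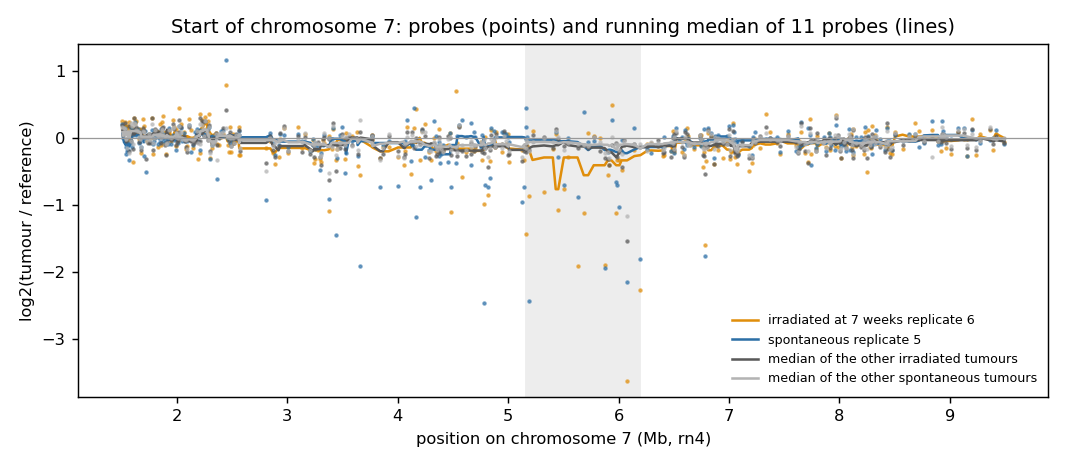
Log2 ratio of tumour over reference DNA (y axis) of probes (points) and their running median (lines) at the start of chromosome 7 (x axis, Mb, rn4) in 7-week replicate 6, spontaneous replicate 5 and the medians of the other irradiated and the other spontaneous tumours, with the 28-probe stretch shaded. The low means of 7-week replicate 6 (-0.68) and spontaneous replicate 5 (-0.42) come with scattered probes below -1, and the medians there are -0.37 and -0.082.

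Focal calls numbered 22.4 ± 28.0 (SD, n = 14) in irradiated and 35.0 ± 16.5 (SD, n = 7) in spontaneous tumours (exact permutation p = 0.312). Without 3-week replicate 2, which had 112, the difference went from -12.6 to -19.5 calls (exact permutation p = 0.00641, n = 13 and 7 tumours). The spontaneous tumours averaged 23.5 focal calls on scan day 5 and 50.3 on scan day 6. With random noise added until all arrays were equally noisy, the difference between irradiated and spontaneous tumours was 1.36. Added noise takes away calls near the Z limit and can shrink a difference of any source. This value therefore does not settle whether array noise set the direction. With residuals shuffled along the genome, false calls averaged 11.6 per irradiated and 27.4 per spontaneous array. Many focal calls may therefore be false, and most held 5 probes, the fewest allowed. Implanted segments of log2 0.25 over 10 probes were also found less often in irradiated than in spontaneous arrays. Recurrent regions numbered 64, 13 of gain and 51 of loss, and 44 included a spontaneous tumour. Most of these regions also spanned only 5 probes. Those with the most tumours were the chromosome 1 gain (7 tumours) and losses on chromosome 7 from 5873330 to 5977497 (7 tumours), chromosome 4 from 68680676 to 68741202 (6 tumours, 3 irradiated and 3 spontaneous) and chromosome 5 from 165671871 to 165707445 (6 tumours, 5 irradiated and 1 spontaneous). Of the 64, 1 had an unadjusted Fisher's exact p under 0.05, a loss on chromosome X from 152667778 to 152894945 in 0 irradiated and 3 spontaneous tumours (p = 0.0263), and 0 passed the adjustment (smallest adjusted p = 0.8). With normexp 1 region passed. A region called in 2 tumours cannot give a Fisher's exact p under 0.1, and most regions had calls in so few. Few regions could therefore have passed, and the count of 0 does not argue against a difference between the groups.

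Tumours irradiated at 3 and at 7 weeks of age were compared with each other in the same way. Large calls numbered 1.86 ± 2.27 (SD, n = 7) and 1.00 ± 0.816 (SD, n = 7), and the difference did not exceed the spread (exact permutation p = 0.484). On the scan days that held both groups the difference was 1.75 (exact permutation p = 0.267). On day 1 the means were 2 and 0.5 calls, and on day 2 they were 3.5 and 1.5. With a segmentation threshold of 8 the difference was -0.286, and without 3-week replicate 3 it was 0.167. The chromosome 4 elevations of 3-week replicates 3 and 1 were each divided into several large calls. These tumours had 6 and 4 large calls, so the 3-week count exceeds the number of separate changes. Large calls covered 1.22% ± 2.74 and 0.0623% ± 0.0832 of the probes (exact permutation p = 0.392, n = 7 and 7), a difference of 1.16 percentage points that was 2.06 within scan days (exact permutation p = 0.167) and 0.133 without 3-week replicate 3. Focal calls numbered 32.1 ± 38.2 and 12.7 ± 4.61 (exact permutation p = 0.190, n = 7 and 7). Within scan days their difference was 20.4 (exact permutation p = 0.944), and the days went opposite ways, with means of 60.5 and 17 on day 1 and 9.5 and 12.25 on day 2. The pooled difference was 19.4, without 3-week replicate 2 it was 6.12, and with all arrays equally noisy it was -0.429. At least 1 large call was present in 5 of 7 tumours of either group.

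Along the genome, 0 of 2728 bins of 1 Mb differed between irradiated and spontaneous tumours with limma at an adjusted p of 0.05, and 357 had an unadjusted p under 0.05. These 357 exceed a share of 0.05 of the bins, the share that tests without any difference would average. Bins of 1 array are not independent, and group went with scanner, so the source of this excess cannot be told apart. The bins named next did not pass. The smallest adjusted p, 0.0596, was shared by bins on chromosome 13 from 33000001 to 34000000 (log2 difference 0.040 ± 0.00787, SE), chromosome 10 from 41000001 to 42000000 (0.059 ± 0.0119) and chromosome 18 from 42000001 to 43000000 (0.036 ± 0.00719). Bins on chromosomes 3 and 2 completed the 5 higher ones, with differences of 0.033 and 0.035. The 5 lower ones were on chromosomes 9, 2, 7, 17 and X, with differences of -0.026 to -0.051 and limma adjusted p of 0.0746 to 0.143. This count depended on the processing, with 238 bins past the threshold after normexp and 78 with array quality weights. Leaving out 1 tumour gave 10 bins without 7-week replicate 4, 6 without 3-week replicate 1, 5 without 3-week replicate 5, and 1 each without 3-week replicate 3 or spontaneous replicate 3. Scan day as a random block left 0, with 209 bins at an unadjusted p under 0.05. Between 3-week and 7-week tumours limma called 0 bins, with 133 at an unadjusted p under 0.05 and a smallest adjusted p of 0.694. These 133 are close to a share of 0.05 of the bins. The bins with the smallest p were on chromosome 1 from 1000001 to 2000000 (log2 difference 0.070 ± 0.0167, SE), higher in 3-week tumours, and on chromosome 17 from 47000001 to 48000000 (-0.028 ± 0.00715), lower in them. The remaining bins taken by the rule, on chromosomes 6, 15, 12 and 3 on the higher side and 14, 3, 15 and 9 on the lower side, differed by 0.022 to 0.055 and by -0.028 to -0.039. With scan day as a block it called 0, with 109 at an unadjusted p under 0.05, and with 1 value per rat it called 1.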

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

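Values that stood far from the rest of their group were sought in 84 groups of 7 tumours, and 13 were found. Of these, 8 came from 75 groups taken without regard to their values, where independent groups would give about 3.75 by chance. Chromosomes of 1 array share its centring and need not be independent. The other 5 came from 9 groups on stretches of chromosomes 3, 5 and 7 that had been chosen for an extreme call, so no chance count applies to them. The tests of equal array noise, of the 2 tumours of 1 rat for focal calls and of the slide were set before their results were seen. All other tests in this part were chosen after the result was seen.

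The losses on chromosome 5 were the deepest values. Over the shared part 3-week replicate 1 averaged -2.51, against -0.82 to 0.0067 in the other 3-week tumours. A flaw on 1 part of the slide is argued against for 3-week replicate 1, because the spots of its 17 lost probes lay 93.1% as far apart as randomly drawn spots. All arrays have the same layout, and 13 of the 21 lost probes of 3-week replicate 4 are among these 17. Their scatter argues against such a flaw for that part of its loss too, while its other probes were not tested. A germline deletion is argued against for 3-week replicate 4, since the other tumour of its rat averaged 0.018 over the same probes. For 3-week replicate 1 there were 0 other tumours of the rat, so a germline and a tumour-specific deletion cannot be told apart. A deletion acquired in the tumour may be the source of the loss in replicate 4, though a slide flaw was not tested for its probes outside the shared part. A relation to irradiation was not shown with 2 carriers: the shared part was called in 2 of 14 irradiated and 0 of 7 spontaneous tumours (Fisher's exact p = 0.533), and its mean had exact permutation p = 0.639 for that comparison and 0.142 for 3-week against 7-week tumours.

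The low values at the start of chromosome 7 were -0.684 in 7-week replicate 6 and -0.424 in spontaneous replicate 5, against -0.292 to -0.100 and -0.190 to -0.0763 in the other tumours of their groups. With normexp they were -0.198 and -0.305, and with dim probes left out the latter was -0.253. A baseline of equal size on all arrays is argued against as the whole source, because 5 tumours, 4 irradiated and 1 spontaneous, had a call after the probes' medians were subtracted. The subtraction leaves in a shared baseline whose size varies between arrays, so that kind stays open for these calls. A few probes with extreme ratios may carry those calls: after the same subtraction the lowest median over the stretch among these 5 tumours was -0.132, above the limit of -0.2 for a call, although before it the median of 7-week replicate 6, -0.368, was the lowest of the 21 tumours. A germline difference of single rats stays open, as 0 of the tumours with such a call have a second tumour of the same rat on an array. Loss calls overlapped the stretch in 8 of 14 irradiated and 4 of 7 spontaneous tumours (Fisher's exact p = 1), and the mean of the stretch differed by -0.0688 between these groups, within the spread (exact permutation p = 0.319).

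The focal counts held 1 value far from the rest, 112 calls in 3-week replicate 2 against 6 to 43 in the other 3-week tumours. For the lower focal count of irradiated than spontaneous tumours, array noise stays open as a source. The difference went from -12.6 to 1.36 calls at equal noise, but added noise takes away calls near the Z limit and can shrink any difference. Outlying single probes may add to the lower count: with residuals shuffled along the genome, false calls differed by -15.8 per tumour, in the direction of the measured difference. Germline differences from the reference animals cannot be told apart, because the tumours of 1 rat shared focal calls with Jaccard indices of 0.0238 and 0.0414 against a median of 0.025 and a 90th percentile of 0.134 in other irradiated pairs. Irradiation itself stays open, as it goes with the scanner.

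The other distant values are given without explanation. Large calls covered 7.37% of the probes in 3-week replicate 3 (others 0 to 1.09%) and 0.0795% in spontaneous replicate 5 (others 0 to 0.0105%). Chromosome 4 averaged 0.0994 in 7-week replicate 1 (others -0.0178 to 0.00527). Chromosome 10 averaged 0.125 in 3-week replicate 5 (others -0.00359 to 0.0265). In 3-week replicate 3, chromosome 16 averaged -0.0454, chromosome 17 -0.0290 and the stretch on chromosome 3 from 111761402 to 113371553 -0.0490. That tumour was also the lowest of the 21 on chromosomes 2, 9, 11, 14 and 15, among others, so its low values may not be separate. Chromosome 20 averaged -0.0162 in spontaneous replicate 5 (others 0.00367 to 0.0164). The same stretch on chromosome 3 averaged -0.655 in 7-week replicate 5 (others -0.134 to 0.0243).

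Other splits of the tumours were set against the limma counts. For irradiated against spontaneous tumours the real count was 0 bins and the highest of the other splits gave 1. For 3-week against 7-week tumours the real count was 0 and the highest of the other splits gave 215. With a real count of 0, all 100 of 100 splits in either comparison necessarily gave as many, so this test says nothing about chance. The split with 215 bins may point to a structure of the samples, but it is 1 of 100 and no structure was tested.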

How the results depend on the processing

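Equal noise, single probes, numbers 1 to 4 without the block, probe medians, joined calls, the limit for chromosome shifts and the rule for calls that stand apart were alternatives chosen after seeing the data. Differences are irradiated minus spontaneous or 3-week minus 7-week. No alternative turned the direction of the share of probes in large calls (0.522 to 1.09 and 1.02 to 2.06 percentage points) or brought a whole-chromosome or chromosome-mean difference past the threshold. With normexp the difference in large calls was -0.143 and in tumours with a large call -21.4 percentage points, 1 recurrent region passed and limma called 238 bins. With dim probes left out the difference in tumours with a large call was 57.1 percentage points, with 1 Mb bins in place of segmentation 64.3, and with probe medians subtracted 7.14. With equal noise the focal differences were 1.36 and -0.429. With a threshold Z of 8 the 3-week minus 7-week difference in large calls was -0.286. For irradiated against spontaneous tumours limma called 7 bins with centring on chromosome medians, 6 with segment means, 78 with array quality weights and 5977 of 94711 single probes, and for 3-week against 7-week tumours 1 bin with 1 value per rat. The cause was not tested in any of these.

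Leaving out each tumour in turn gave, for irradiated against spontaneous, 0.648 to 1.26 large calls, 0.111 to 0.678 percentage points of probes, -19.5 to -9.40 focal calls (-19.5 without 3-week replicate 2, exact permutation p = 0.00641), 38.1 to 54.8 percentage points of tumours with a large call (54.8 without spontaneous replicate 4 or 5), 0 to 7.69 percentage points of tumours with a whole-chromosome aberration, 0 to 0 chromosomes, 0 to 0 recurrent regions and 0 to 10 limma bins. The bins were 6 without 3-week replicate 1, 1 without 3-week replicate 3, 5 without 3-week replicate 5, 10 without 7-week replicate 4 and 1 without spontaneous replicate 3. For 3-week against 7-week it gave 0.167 to 1.17 large calls, 0.133 to 1.36 percentage points of probes, 6.12 to 23.8 focal calls and 0 to 0 bins.

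Tumours of the same replicate number correlated at -0.211 to 0.497 between 3-week and 7-week tumours. Of 7 pairs, 4 lay over 0.1 (other numbers 15 of 42). Numbers 1 to 4 of these groups shared scan days, so pairing stays open. Irradiated and spontaneous pairs gave -0.355 to 0.425, with 3 of 8 over 0.1 (28 of 90). With the replicate block over numbers 1 to 4 the focal difference was 1, against -12.6 over all tumours. The same tumours without the block gave 1 by construction, since each number holds every group once. The change comes from the tumours left out. Spontaneous replicates 5 to 7 among them, read on scan day 6, averaged 50.3 focal calls against 23.5 on day 5. With the block limma called 0 bins in both comparisons and no other call changed. The 40 values of single chromosomes and stretches under alternatives all kept their sign. With normexp the deepest loss, on chromosome 5 in 3-week replicate 1, was -1.79 in place of -2.46, chromosome 4 in 3-week replicate 3 was 0.42 in place of 0.32, and chromosome 10 in 3-week replicate 5 was 0.17 in place of 0.13. The low chromosome 7 values moved to -0.198 in 7-week replicate 6 and -0.305 in spontaneous replicate 5 with normexp and -0.253 in the latter with dim probes left out. Gene lists, the planned locus, GC content and genes with several probes were not run, and the slide was not a block for single values. Cy3 signals 8.51 to 16.1 times above background may limit small ratios, which was not tested. Shifts of log2 0.1 lie below the limit of 0.2 for a call, so they could not be called.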

Other observations

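On chromosome X, 10 probes from 128806820 to 130532267 averaged -0.21 ± 0.0890 (SD, n = 14) in irradiated and -0.19 ± 0.0530 (SD, n = 7) in spontaneous tumours, below 0 in all 21 (exact permutation p = 0.659). A loss on chromosome 2 from 86498250 to 87669759 overlapped calls in 7 irradiated and 5 spontaneous tumours (Fisher's exact p = 0.642), with means of -0.11 ± 0.105 and -0.13 ± 0.119. Other recurrent regions included a gain on chromosome 1 from 47812502 to 48079454, called in 5 tumours, and a loss on chromosome 18 from 80983366 to 81146183, called in 4 tumours irradiated at 3 weeks and 1 spontaneous tumour (adjusted Fisher's exact p = 1). Losses on chromosome 8 from 32309677 to 32481947 and on chromosome 1 from 157095460 to 157172316 were each called in 3 tumours irradiated at 3 weeks and 1 spontaneous tumour, as was a loss on chromosome 2 from 201028004 to 201096712. A loss on chromosome 3 from 69946797 to 69995971 was called in 2 irradiated and 2 spontaneous tumours. Losses on chromosome 7 from 3839785 to 4753400 (2 irradiated, 1 spontaneous) and on chromosome X from 128806820 to 129212385 (1 irradiated, 2 spontaneous) completed the 12 regions taken by tumour count and then by width. In all, 12 regions had calls in 3 tumours, and these were the widest of them.

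Across all probes the log2 ratios of different tumours correlated with each other, with a median correlation of 0.552 over 210 pairs (range 0.184 to 0.831). Probes are not independent replicates, and all arrays share the reference DNA. Pairs read on the same scan day had a median of 0.654 (33 pairs) and other pairs 0.539 (177 pairs). The 2 pairs of tumours from 1 rat lay at 0.448 and 0.773.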
